A study of Mus musculus with 22 samples.

How the data were processed

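RNA was sequenced from mouse embryonic stem cells in 22 libraries of 8 groups. There were 2 libraries each of NF45 WT and NF45 KO cells, prepared with a stranded poly(A) kit, and 3 libraries each of input RNA and of RNA immunoprecipitated with an antibody against NF90/NF110 in NF90/NF110 WT, NF110 KO and NF90+NF110 KO cells, prepared with a ribosomal RNA depletion kit. The study text calls the replicates biological; whether they came from separate cultures or clones is not given in the sources used here, so every p-value measures the spread between these libraries only. Each immunoprecipitation (IP) and its input come from the same experiment by the study's design, giving 9 pairs. As a check, the correlation of each IP with its own input over genes, after the group means were removed, ran from 0.55 to 0.84, and the best match was the own input in 5 of 9 pairs. Inputs with the same number in different genotypes had correlations from -0.469 to 0.65 over 9 pairs. For number 3 they were all positive (0.645, 0.49 and 0.65), so pairing across genotypes is neither shown nor excluded, and the main fit assumed none. The NF45 libraries carry a number only.

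The authors name TopHat2 2.0.10, Cufflinks 2.2.1, Cuffnorm, HTSeq 0.6.1, DESeq2 and the mm10 build. Their order and which of them made which value are not given in the sources used here, except that a file header names DESeq2 for the comparisons. The deposited FPKM table gives fragment density, scaled to transcript length and library size, for 22330 genes. The second deposited table gives normalised counts (signal), which are whole reads divided by a size factor per library; 100% of the nonzero values in each library came within 0.1 of a whole number after division by that library's smallest value. Per the file headers it also holds the log2 fold change and its standard error, the Wald statistic (a score), and the p-value and adjusted p-value of each comparison the authors made. Per the file headers, the libraries named Rev are NF45 WT. What Rev stands for is not given in the sources used here, so a control line derived from the KO cells is not excluded, and every NF45 comparison is with the libraries so labelled.

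Genes were placed on the GRCm38 mouse genome by symbol (21147) or by symbol or synonym (22217). The values analysed were log2(FPKM + 1) of genes with FPKM of at least 1 in at least 2 NF45 libraries or at least 3 libraries of the RIP-seq set. Testing used limma 3.58.1 in R 4.3.3, with a variance trend and robust moderation, and called a gene changed at a Benjamini-Hochberg adjusted p under 0.05. The fits covered 4 libraries for NF45 (11481 genes, 2 residual degrees of freedom), 9 inputs (12444 genes, 6) and 18 inputs and IPs with a term per experiment (12693 genes, 6), the last also giving the differences in enrichment between genotypes. Each test allowed for a change in either direction, except the overlap of genes called in NF45 KO and NF90+NF110 KO, tested for an excess only.

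For genes named in the text the rule was the targeted genes always, then the 8 largest changes in each direction among genes past the threshold with a mean FPKM of at least 1 and no overlap between the groups' libraries, skipping predicted and clone-named genes, then up to 4 members of each gene list that passed its set test or had 3 called members, up to 3 members of the pluripotency, germ layer, trophectoderm and interferon lists, and 6 genes of each overlap. In all, 28 gene lists were written down, and 24 or 25 could be tested in each comparison. Set tests used camera with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. With the preset correlation 63 of the set tests over the 10 comparisons passed, and with the estimated correlation 0 did. The estimated version judges each list on the residual degrees of freedom of its fit (2 or 6), the preset version on the number of genes. Passing the former after adjustment is hard, so failing it does not show that correlation between genes accounts for a list's shift. The groups, comparisons, test, gene lists and naming rule, and the alternatives of filter, pseudocount, scaling, replicate block, minimum fold and left-out replicates, were fixed before the data were examined. Whole reads recovered from the normalised counts were tested with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 as added alternatives. Fits without the genes of chromosomes 6, 8, 13, 14 and Y, with libraries centred per chromosome, with the level of chromosome 6 genes as a continuous term, and with a trend against gene length and level removed were also added after seeing the data.

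Reads assigned to genes came to 49.1 to 68.8 M per NF45 library, 9.5 to 11.9 M per input and 14.1 to 19 M per IP. On simulated data with the spread of these libraries, limma recovered 20.9% of changes of 0.5 on the log2 scale, 65.7% of changes of 1 and 90.9% of changes of 2 for NF45, with 3.3% false among its calls. For the NF90+NF110 KO inputs it recovered 43.3% of changes of 0.5 and 92.5% of changes of 1, and for the difference in enrichment between WT and NF90+NF110 KO 59.7% of changes of 0.5 with 7.5% false. edgeR on NF45 reads made 11.6% false calls. For limma the changes were planted only in genes with a mean log2(FPKM + 1) above 2. In all simulations the spread was drawn for each gene alone. The rates thus leave out differences that many genes of a library share, and those of limma also leave out changes in lower genes. Transcript isoforms were not analysed here, since both tables give a single value per gene. Some results that this rule names are not reported here.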

Results

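The data describe mouse embryonic stem cells, kept with LIF and inhibitors of MEK and GSK3, that lack NF45 or its partners NF90 and NF110. NF45 is the product of Ilf2 and forms double-stranded RNA-binding complexes with NF90 and the longer NF110. RNA-seq compared NF45 KO with NF45 WT cells (n = 2 each). RIP-seq, which sequences the RNA that comes down with an antibody, compared input and IP in NF90/NF110 WT, NF110 KO and NF90+NF110 KO cells (n = 3 each). Genes with FPKM of at least 1 numbered 11190 to 11354 per NF45 library, 12061 to 12210 per input and 11857 to 12172 per IP. The 10 genes with the most reads took 3.3% to 3.4%, 3.9% to 4.3% and 4.6% to 5.7% of the reads assigned to genes. FPKM of the ribosomal RNA precursor Rn45s ran from 40.3 to 146 in the NF45 libraries, 914 to 1745 in inputs and 1048 to 2790 in IPs. It moved with genotype. In inputs it was 1383 to 1651 in WT, 1451 to 1745 in NF110 KO and 914 to 1065 in NF90+NF110 KO, and in IPs 2270.1 to 2790, 1809.7 to 2308 and 1048 to 1218. Whether ribosomal RNA left in the libraries bears on the differences in enrichment was not tested. Values below are means ± SD in FPKM and log2 fold changes with the limma standard error (SE).

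Loss of the NF45 transcript was read from Ilf2 (chromosome 3, 90476201 to 90488379 on GRCm38). Ilf2 fell from 286 ± 30.6 in NF45 WT to 3.86 ± 0.096 in NF45 KO (log2 fold change -5.88, SE 0.09, adjusted p = 0.000581). Directions for the libraries labelled NF110 KO and NF90+NF110 KO rest on their labels.

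NF45 KO against NF45 WT asks which RNAs change when NF45 is lost. The largest rises included Ephx2, the soluble epoxide hydrolase (78.2 ± 2.6 against 14.4 ± 8.1; log2 fold change 2.46, SE 0.38, adjusted p = 0.0164), and Lef1, a transcription factor of Wnt signalling (5.11 ± 0.77 against 0.224 ± 0.037; 2.31, SE 0.13, adjusted p = 0.00693). Plk2, a polo-like kinase, rose from 13.8 ± 0.39 to 57.7 ± 2.5 (1.99, SE 0.06, adjusted p = 0.00443). Serpine2, a protease inhibitor, and Cd80, a ligand of T cell costimulation, rose by 2.00 and 2.10 on the log2 scale. Also among the 8 largest rises were Mup6 (2.21) and Zscan4a (2.15), which have near-identical copies elsewhere in the genome. The deepest fall after Ilf2 was that of H2afy, which encodes the histone variant macroH2A1 (chromosome 13, 56073622 to 56135626; 8.69 ± 0.44 against 155 ± 38; -3.99, SE 0.18, adjusted p = 0.00566). Pnma5 (-3.21), the imprinted gene Mest (-2.78, on chromosome 6), Fam111a (-2.46), Etv4, an ETS factor induced by FGF and ERK signalling (-2.42), and the PRAME-like genes Pramel7 (-2.53) and Pramel6 (-2.41) followed. In all, 3171 of 11481 genes changed, 1338 higher and 1833 lower in NF45 KO, and 368 of them by at least 2-fold (211 higher, 157 lower). Without either KO library limma called 0 genes (2291 and 2316 at an unadjusted p under 0.05; no other tool was run with a library left out). Without WT library 1 or 2 it called 6035 and 5223.

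The p53 target list rose. Of its 23 measured members 19 rose and 0 fell, counted over all genes and also adjusted over the list alone, with a median log2 fold change of 0.96 (set test adjusted p = 5.5e-10, adjusted p = 0.835 with an estimated correlation). Beside Plk2 and Cd80 these included Pmm1, a phosphomannomutase (281 ± 1.5 against 99.6 ± 4.0; 1.49), Ccng1, cyclin G1 (1.07), and Btg2, an antiproliferative gene (0.96). All 10 measured genes of the 2-cell list, which are active in the 2-cell embryo, rose, also adjusted over the list alone (median 1.44; set test adjusted p = 1.3e-08, adjusted p = 0.835 with an estimated correlation). These 10 met the FPKM minimum only through both KO libraries, so the filter largely fixed their direction and this set test. Over all 23 2-cell genes with a value above 0, medians over pairs of a KO and a WT library were 0.783 or more. Those medians were added after seeing the data. Tmem92 went from 0.0792 ± 0.035 to 2.99 ± 0.66 and Zscan4d from 0.121 ± 0.11 to 3.01 ± 0.22, so the levels stayed low. Both lists kept these directions under quantile scaling and median centring, with 19 p53 targets and 10 2-cell genes called higher under each. Without either KO library 0 of the 23 p53 targets were called, though 21 or more kept a positive fold change, and the 2-cell genes no longer reached the FPKM minimum in 2 libraries.

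**Figure D1:**
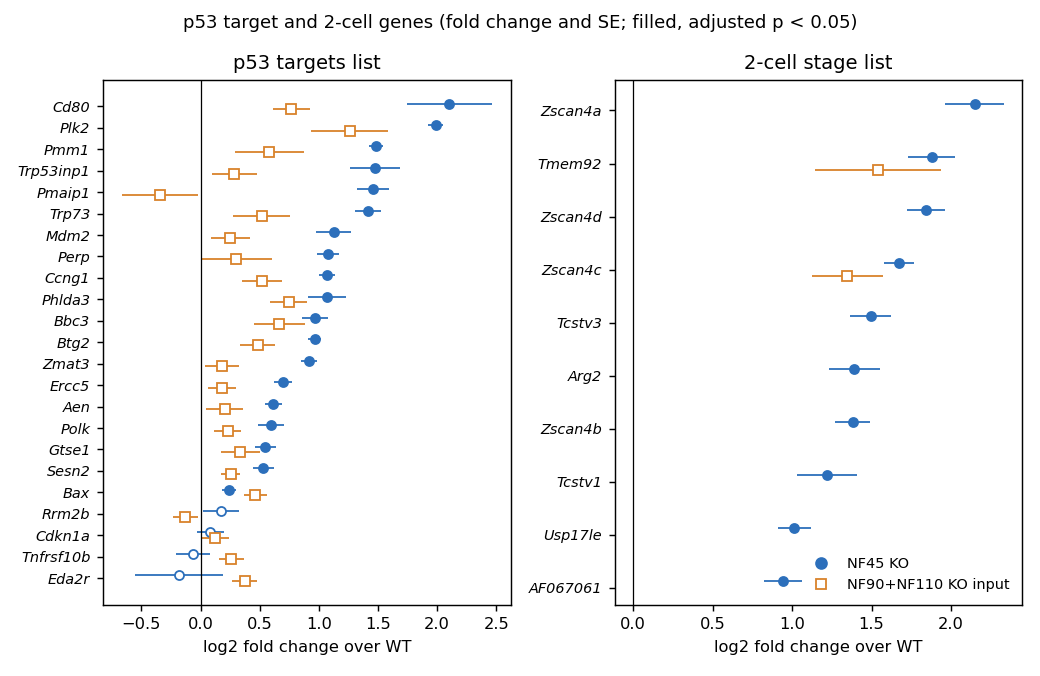
log2 fold change with SE of the p53 target genes (left) and 2-cell genes (right) in NF45 KO over NF45 WT (circles) and in NF90+NF110 KO over NF90/NF110 WT inputs (squares), with filled points at an adjusted p under 0.05. Of the 23 p53 targets 19 are filled in NF45 KO and 0 in the inputs, where only Zscan4c and Tmem92 of the 2-cell genes were tested.

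Genes of the ATF4 and unfolded protein response fell in NF45 KO: 10 of 21 were lower and 2 higher (13 and 2 adjusted over the list alone; set test adjusted p = 0.0017, adjusted p = 0.847 with an estimated correlation). Herpud1, a factor of protein degradation at the endoplasmic reticulum (6.78 ± 0.20 against 32.8 ± 1.2; -2.12), and the amino acid transporter gene Slc7a5 (-1.48) lie on chromosome 8, and the disulfide isomerase gene Pdia4 (-0.92) lies on chromosome 6, while Atf3 (-1.26) lies on chromosome 1. Outside chromosomes 6, 8, 13, 14 and Y 7 of 17 members were lower. Cytosolic ribosomal protein genes shifted up slightly, with 11 of 73 higher and 1 lower (3 and 0 adjusted over the list alone; median 0.14; set test adjusted p = 0.000836, adjusted p = 0.835 with an estimated correlation), among them Rps27l, itself a p53-responsive paralog (0.40). Of the G1/S list 8 of 26 fell, including the replication licensing gene Mcm2 (-0.64), but outside the chromosomes just named 3 of 19 fell, and the set test did not pass (adjusted p = 0.093).

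Pluripotency and lineage genes moved in both directions. Of 30 pluripotency genes 4 rose and 6 fell (8 and 7 adjusted over the list alone). The set test did not pass (adjusted p = 0.516). Tdgf1, the Nodal co-receptor Cripto (626 ± 43 against 414 ± 18; 0.59), and Sall4 (0.47) rose, and Tcl1, an AKT cofactor (103 ± 16 against 186 ± 15; -0.85), fell. Nanog, on chromosome 6, was at 624 ± 3.6 against 783 ± 13 (-0.33, adjusted p = 0.0144), but at 0.17 once each library was centred per chromosome. The primed epiblast list rose in 3 of 11 members and fell in 1, both also adjusted over the list alone (set test adjusted p = 0.032, adjusted p = 0.835 with an estimated correlation), with Lef1 above and Otx2, a factor of the epiblast and forebrain, at 22.0 ± 2.7 against 8.81 ± 4.3 (1.30). In the ectoderm and neural list 3 of 6 fell and 0 rose. They were Tubb3 (-1.67) and Sox1 (-1.06), both on chromosome 8, and the intermediate filament gene Nes (6.21 against 13.5 ± 1.7, adjusted p = 0.00783). Trophectoderm genes split into 5 higher, with Krt7 (1.77), Ascl2 (1.62) and Krt19 (1.04), and 4 lower, with Tead4 on chromosome 6 (-0.80). Of the endoderm list 2 of 9 rose, Lamb1 (1.36) and Cxcr4 (0.77), and Lama1 fell (-0.59). Of 4 mesoderm genes Bmp4 fell (-0.92). Germ cell genes rose in 3 of 12, namely Mael (1.53), Stra8 (1.11) and Sycp3 (0.66). In the interferon and double-stranded RNA list 4 of 15 fell and 0 rose, including the antiviral tetherin gene Bst2 (-2.29, on chromosome 8) and the RNA-activated kinase gene Eif2ak2 (-0.31). None of the trophectoderm, endoderm, mesoderm, neural, germ cell and interferon lists passed its set test (adjusted p = 0.819, 0.704, 0.831, 0.308, 0.143 and 0.424). In the list of 14 NF90 family members and partners, which holds Ilf2 itself, 5 fell and 1 rose (5 and 2 adjusted over the list alone), and the set test did not pass (adjusted p = 0.674). Dhx9, an RNA helicase (115 ± 0.36 against 223 ± 13; -0.95), fell, and Zfr, whose protein shares a dimerisation domain with NF45 and NF90, rose (81.4 ± 0.67 against 47.6 ± 1.6; 0.76). Of 6 measured fibroblast and feeder cell markers 2 rose, and their set test did not pass (adjusted p = 0.203).

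Expression moved by chromosome as well. The median log2 fold change in NF45 KO was -0.48 over the 542 genes of chromosome 6 and -0.50 over the 630 genes of chromosome 8, and these 2 chromosomes hold 756 of the 1833 genes called lower (41.2%). The medians of -0.24 and -0.25 for chromosomes 13 and 14 come from NF45 WT library 2 alone. Its median log2 deviations there were 0.379 and 0.388, against -0.132 and -0.147 in WT library 1, -0.129 and -0.109 in KO library 1 and -0.088 and -0.098 in KO library 2. The other 16 chromosomes had medians between -0.04 and 0.05 (chromosome Y, with 2 genes, left out). Without the genes of chromosomes 6, 8, 13, 14 and Y, limma called 2726 genes, 1486 higher and 1240 lower.

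**Figure D2:**
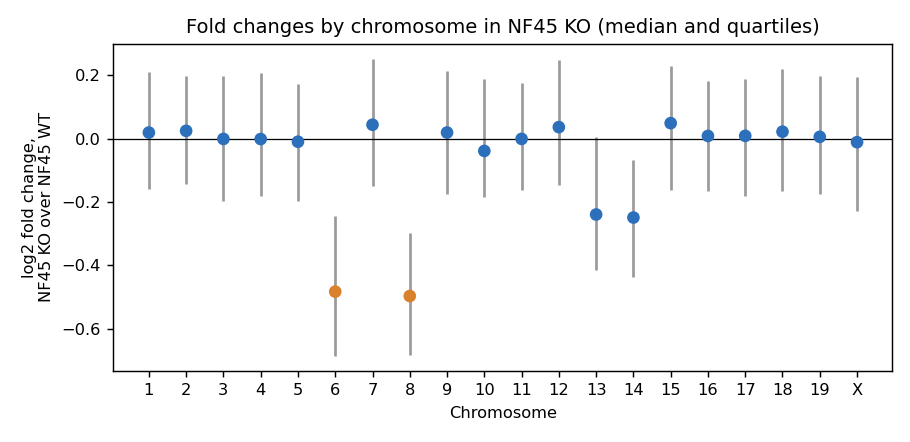
Median log2 fold change of NF45 KO over NF45 WT for the tested genes of chromosomes 1 to 19 and X, with bars from the lower to the upper quartile. Chromosomes 6 and 8 (orange) stand at -0.48 and -0.50, below the others drawn (chromosome Y, with 2 genes, is left out).

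The NF90+NF110 KO inputs against the WT inputs ask what the loss of NF90 and NF110 changes in total RNA. Pcmt1, a repair enzyme of isoaspartate in proteins (chromosome 10, 7627845 to 7681337), fell from 41.3 ± 1.5 to 10.5 ± 1.7 (log2 fold change -1.89, SE 0.12, adjusted p = 0.000578). Zswim6 (-1.17, SE 0.11, adjusted p = 0.00788), Apobec2 (-1.16), Mbtd1 (-0.97), the germ cell Y-box gene Ybx2 (-0.88) and Ide, which encodes an insulin-degrading protease (-0.75), also fell. Dio3, which inactivates thyroid hormone, rose from 25.5 ± 3.0 to 49.0 ± 2.5 (0.92, SE 0.09, adjusted p = 0.00985), followed by Creb3l1 (0.84), the adhesion gene Mcam (0.73), the ephrin gene Efna3 (0.72) and the secreted glutathione peroxidase gene Gpx3 (0.70). Limma called 26 of 12444 genes, 11 higher and 15 lower, 3 of them by at least 2-fold, with 21.5% of genes free of overlap between the groups where chance gives 10% for 3 against 3. The count ran from 1 (without WT input 1 or NF90+NF110 KO input 1) to 23 with a single input left out and was 1 when only the libraries compared were fitted and 309 by DESeq2 on recovered reads. The authors' deposited table passes 655 genes at the same threshold, 26 of them shared with limma.

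Of the 23 p53 targets in these inputs 0 passed over all genes and 9 passed as higher adjusted over the list alone (median 0.30; set test adjusted p = 1.7e-08, adjusted p = 0.323 with an estimated correlation). Phlda3 stood at 62.3 ± 9.1 against 36.8 ± 6.5 (0.75, adjusted p = 0.108), Cd80 at 0.77 (adjusted p = 0.102), Bax at 0.46 (adjusted p = 0.102) and Plk2 at 1.26 (adjusted p = 0.152). The 80 ribosomal protein genes had a median of 0.18 with 0 called (set test adjusted p = 1.7e-08, adjusted p = 0.72 with an estimated correlation). The 19 microRNA pathway genes had a median of -0.15 with 0 called and 1 lower adjusted over the list alone (set test adjusted p = 0.00605, adjusted p = 0.29 with an estimated correlation). Of 30 pluripotency genes 0 were called (set test adjusted p = 0.722), and Nr0b1 was at 0.30 (adjusted p = 0.173). These counts of 0 come from limma, with 1840 genes at an unadjusted p under 0.05.

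In the NF110 KO inputs limma called a single gene against WT, Gm16853, a predicted noncoding gene named after its value was seen (3.73 ± 0.90 against 0.608 ± 0.13; 1.54, adjusted p = 0.0331). At an unadjusted p under 0.05 there were 2043 genes, 22.6% were free of overlap, edgeR called 0, DESeq2 on recovered reads 272, and the authors' deposited table passes 554. Partners of the NF90 family shifted down as a list of 14, with 0 called and 5 lower adjusted over the list alone (set test adjusted p = 0.000291, adjusted p = 0.348 with an estimated correlation). Its members include Dhx9 (-0.32, adjusted p = 0.173) and the nuclear matrix gene Matr3 (-0.47, adjusted p = 0.177). Replication-dependent histone genes shifted up with 0 of 61 called (median 0.21; set test adjusted p = 1.8e-09, adjusted p = 0.521 with an estimated correlation). The 290 KRAB and other C2H2 zinc finger genes shifted down with 0 called and 18 lower adjusted over the list alone (median -0.13; set test adjusted p = 3.8e-09, adjusted p = 0.255 with an estimated correlation).

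NF90+NF110 KO against NF110 KO inputs sets the loss of both isoforms against the loss of NF110 alone. These inputs also differed in genes of chromosome 6 (median log2 fold change -0.16) and of chromosome Y (-1.23 over 4 genes). The further loss of NF90 is thus not isolated. Pcmt1 (-1.46, SE 0.12, adjusted p = 0.00392), Macrod1, an ADP-ribose hydrolase gene (-0.93), Zswim6 (-0.92) and Lefty1, a Nodal antagonist (67.2 ± 5.6 against 120.4 ± 6.3; -0.83), fell. Limma called 6 of 12444 genes, with 1292 at an unadjusted p under 0.05 and 14.7% free of overlap. It called 0 without NF110 KO input 2, and 0 when only the libraries compared were fitted, with 649 and 1083 genes at an unadjusted p under 0.05. DESeq2 on recovered reads called 80, and the authors' deposited table passes 140.

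The level of chromosome 6 genes differed between replicates of each RIP-seq genotype. Its median log2 deviation lay between 0.23 and 0.27 in WT input 1, NF110 KO inputs 1 and 2 and NF90+NF110 KO input 2, between -0.24 and -0.16 in the other 5 inputs, and at like values in the IPs of the same experiments. Genes of chromosome Y also differed between cultures. Ddx3y stood at 0, 0.0368 and 5.52 in NF90+NF110 KO inputs 1, 2 and 3, and at 4.48, 5.08 and 6.20 in the WT inputs, and Eif2s3y at 0, 0 and 4.39, against 8.62, 3.80 and 6.66. Over the 4 tested genes of chromosome Y the median log2 fold change of NF90+NF110 KO inputs was -1.46 against WT and -1.23 against NF110 KO. By limma neither Ddx3y (adjusted p = 0.2603, unadjusted p = 0.0231) nor Eif2s3y (adjusted p = 0.174, unadjusted p = 0.00647) passed against WT. With this level as a continuous term, added after seeing the data, limma called 1031 genes in NF90+NF110 KO and 717 in NF110 KO inputs against WT. In that fit 12 of 23 p53 targets were higher in NF90+NF110 KO and 5 in NF110 KO, among them Phlda3 (0.72, adjusted p = 0.000499, and 0.35, adjusted p = 0.0306).

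**Figure D3:**
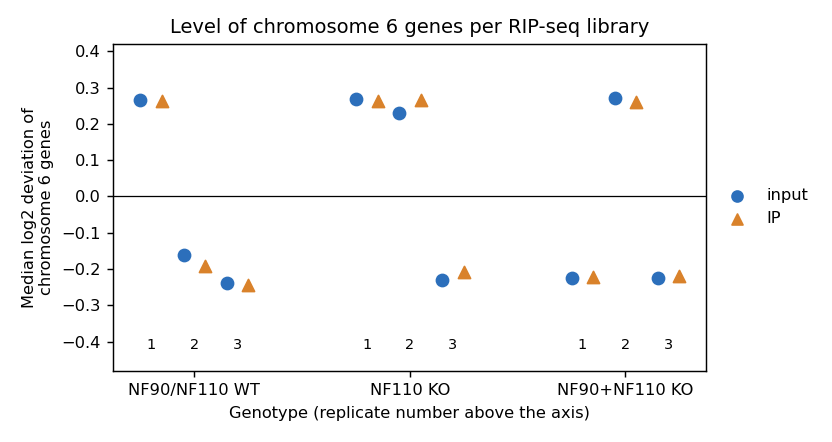
Median log2 deviation of chromosome 6 genes from their mean over the RIP-seq libraries, per library, with inputs as circles and IPs as triangles in order of replicate number. In each genotype the replicates lie on both sides of 0, and each IP lies beside its own input.

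The fold changes of NF45 KO and NF90+NF110 KO were compared to ask how far the partners' losses coincide. Pcmt1 (-2.00 and -1.89), Zswim6 (-1.61 and -1.17), Ide (-1.11 and -0.75) and the lipoprotein gene Apom (-0.87 and -0.70) were lower in both, and Dio3 (1.25 and 0.92) and Mcam (1.13 and 0.73) were higher in both. Of 11226 genes in both tests 6 were higher in both (1.22 expected, Fisher's exact p = 0.000528) and 9 lower in both (2.27 expected, Fisher's exact p = 6.9e-05), and all 15 that passed in both had the same direction. In the fit with the chromosome 6 term, 153 were higher in both (54.5 expected), 150 lower in both (77.4 expected) and 65 opposite. Across all genes, which are not independent replicates, Pearson's r was 0.269 and Spearman's rho 0.232. Without a single library r ran from 0.098 (without WT input 1) to 0.402 (without NF90+NF110 KO input 2). The r against NF110 KO was -0.039, and its range without single libraries was not computed. Chromosome 6 levels were high in NF110 KO inputs 1 and 2 but only in input 1 of WT, so those groups were not balanced in that level. The overlap of called genes says nothing there, since limma called none of these 11226 genes in NF110 KO. NF110 KO and NF90+NF110 KO had an r of 0.552, but they share the WT inputs, and simulated values without any effect gave 0.5. The covariance was 0.0265, against 0.0171 simulated. That simulation leaves out differences that many genes of a library share.

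IP against input in WT cells asks which RNAs come down with the antibody. Rbm42, which encodes an RNA-binding protein, stood at 1100 ± 344 in IP and 61.8 ± 2.1 in input (log2 fold change 4.09, SE 0.13, adjusted p = 4.3e-08). Bub1b, the mitotic checkpoint kinase BubR1, was at 676 ± 240 and 72.0 ± 8.8 (3.16), and Golga4, a golgin, at 202 ± 39.9 and 23.5 ± 2.0 (3.04). Nckap5l (2.86), the COPII coat gene Sec24c (2.46), Synrg (2.24), the formin gene Diap1 (2.19) and the basement membrane gene Nid2 (2.13) completed the 8 largest. The nuclear RNA Malat1 was lower in IP (151 ± 8.3 against 497 ± 91; -1.70, SE 0.07), as were Rbmx (-1.52) and Rpl12 (-1.36). Limma called 6659 of 12693 RNAs, 3663 higher and 2996 lower in IP, but 125 by at least 2-fold (58 higher, 67 lower). Without the term for experiment it called 3491.

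Of 30 pluripotency genes 16 were higher in the WT IP and 1 lower (17 and 1 adjusted over the list alone; set test adjusted p = 0.00541, adjusted p = 0.199 with an estimated correlation), with Klf5 (335 ± 22 against 119 ± 4.1; 1.48), Utf1 (0.70) and Sox2 (0.60). Of 23 Polycomb and chromatin repressor genes 14 were higher and 5 lower, both also adjusted over the list alone (set test adjusted p = 0.0131, adjusted p = 0.199 with an estimated correlation), led by Phc1 (1.95). Ribosomal protein RNAs were lower in 52 of 81 and higher in 10 (54 and 10 adjusted over the list alone; set test adjusted p = 2.9e-07, adjusted p = 0.36 with an estimated correlation), with Rpl32 (-1.12) and Rps25 (-1.01). All 6 host RNAs of small nucleolar RNAs, also adjusted over the list alone, were lower (set test adjusted p = 0.000871, adjusted p = 0.194 with an estimated correlation), with Snhg6 at -1.08. So were 7 of 8 long noncoding RNAs of pluripotent cells, also adjusted over the list alone (set test adjusted p = 0.000658, adjusted p = 0.199 with an estimated correlation), with Dancr at -1.07.

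The same immunoprecipitation was done in NF110 KO cells, which by their label keep NF90, a target of the antibody, and in NF90+NF110 KO cells, where enrichment is background if the label holds. Rbm42 was at 3.30 in NF110 KO and 3.87 in NF90+NF110 KO, Bub1b at 2.72 and 2.98, Golga4 at 2.83 and 3.05, Sec24c at 2.15 and 2.65, and Klf5 at 1.14 and 1.17. Limma called 4832 RNAs in NF110 KO (2677 higher, 2155 lower) and 5655 in NF90+NF110 KO (2971 higher, 2684 lower), 84 and 95 of them by at least 2-fold. Ribosomal protein RNAs were lower in IP in 46 of 81 in NF110 KO (48 adjusted over the list alone; set test adjusted p = 9.8e-08, adjusted p = 0.369 with an estimated correlation). In NF90+NF110 KO 55 of 81 were lower (58 adjusted over the list alone; set test adjusted p = 8.3e-14, adjusted p = 0.338 with an estimated correlation). Enrichment in WT and NF90+NF110 KO correlated across the 12693 RNAs, which are not independent replicates (r = 0.8, rho = 0.763), and of the 4268 RNAs called in both 4178 had the same direction. Without the term for experiment the counts were 1865 and 2433.

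**Figure D4:**
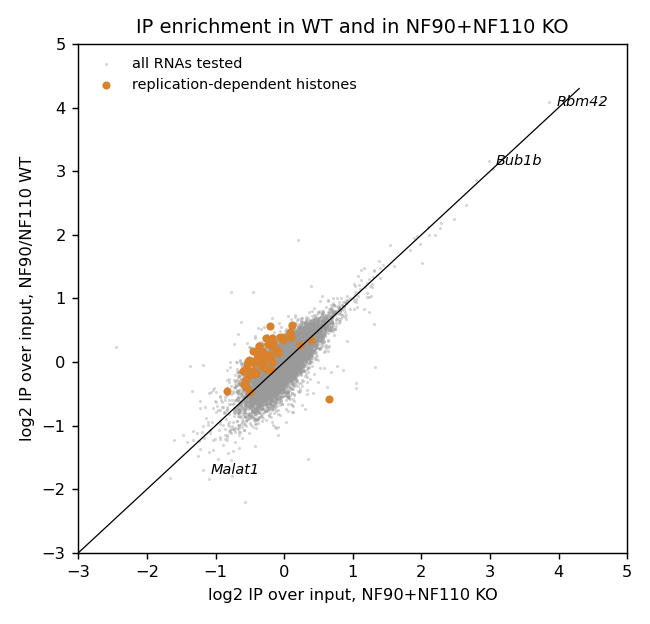
log2 IP over input of each tested RNA in NF90+NF110 KO (horizontal axis) and NF90/NF110 WT (vertical axis), with the replication-dependent histone RNAs in orange and a line where both are equal. Rbm42 and Bub1b lie high in both genotypes, and 34 of 61 histone RNAs pass as more enriched in WT.

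The enrichment in WT minus that in NF90+NF110 KO asks which RNAs depend on the antibody's target. Phlda2, an imprinted growth regulator of the placenta, was at 0.28 ± 0.10 in WT and -0.73 ± 0.19 in NF90+NF110 KO (mean ± SD of log2 IP over input, n = 3; difference 1.02, SE 0.15, adjusted p = 0.0115). Crygd (1.11), Fgf22 (1.27) and Rangrf (0.86) were also higher in WT, and Zfp345 (-0.93), Lsm5, a subunit of the Lsm ring (-0.89), and Cox20 (-0.76) lower. Replication-dependent histone RNAs were higher in WT in 34 of 61 and lower in 0 (48 and 0 adjusted over the list alone; median 0.37; set test adjusted p = 2.7e-20, adjusted p = 0.272 with an estimated correlation), with Hist3h2ba (0.78), Hist1h4j (0.63) and Hist1h4h (0.61). Under quantile scaling 2 of the 61 were called, and 2 without WT experiment 1 or 2 or NF90+NF110 KO experiment 1, and 4 without NF90+NF110 KO experiment 3. With the trend against transcript length and level removed, an alternative added after seeing the data, 1 of the 34 stayed called. Nuclear-encoded genes of oxidative phosphorylation were higher in 10 of 25 (14 adjusted over the list alone; set test adjusted p = 2.2e-07, adjusted p = 0.315 with an estimated correlation; 1 under quantile scaling), with Ndufs3 at 0.44. The zinc finger genes were lower in 11 of 291 (3 adjusted over the list alone; set test adjusted p = 7.3e-10, adjusted p = 0.112 with an estimated correlation). Limma called 739 of 12693 RNAs, 585 higher and 154 lower in WT, 4 by at least 2-fold, with 28.2% free of overlap where chance gives 10%. Leaving out a single experiment gave 13 (WT 2 or NF90+NF110 KO 1), 49 (NF90+NF110 KO 3), 63 (WT 1), 362 (WT 3), 479 (NF110 KO 2) or 1179 (NF90+NF110 KO 2). Quantile scaling gave 135 (75 higher, 60 lower), and a fit without the variance trend or without the term for experiment 0 (2830 and 965 at an unadjusted p under 0.05), against 1173 by edgeR.

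Between NF110 KO and NF90+NF110 KO, Chchd1, a mitochondrial ribosome gene, was more enriched in NF110 KO (0.54 ± 0.095 against -0.245 ± 0.055; difference 0.79, SE 0.07, adjusted p = 0.000477), as were Magohb of the exon junction complex (0.80) and Ssb, the La protein of RNA polymerase III transcripts (0.79), and the imprinted noncoding RNA Meg3 was less so (-0.69). Histone RNAs were higher in 17 of 61 (41 adjusted over the list alone; set test adjusted p = 6.6e-12, adjusted p = 0.556 with an estimated correlation; 1 under quantile scaling). G2/M genes were higher in 8 of 25 (14 adjusted over the list alone; set test adjusted p = 8.3e-07, adjusted p = 0.387 with an estimated correlation), with Nusap1 (0.38) and Mki67 (0.32). Limma called 1258 RNAs, 762 higher and 496 lower in NF110 KO, 1 by at least 2-fold. It called 6 without NF110 KO experiment 2, 7 without NF90+NF110 KO experiment 1 and 396 without NF110 KO experiment 3.

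Between WT and NF110 KO, Rbm42 was more enriched in WT (difference 0.79, SE 0.19, adjusted p = 0.031), as was Phc1 (0.52), while Lsm5 (-1.49), Zfp936 (-1.40), Trappc2 (-1.27) and the histone deacetylase gene Hdac2 (-0.54) were less so. Zinc finger genes were lower in 43 of 291 and higher in 15 (60 and 20 adjusted over the list alone; set test adjusted p = 0.00295, adjusted p = 0.821 with an estimated correlation). Limma called 1694 RNAs, 831 higher and 863 lower in WT, 18 by at least 2-fold. It called 0 without WT experiment 3 or NF110 KO experiment 2 or 3 (2952, 3096 and 2966 at an unadjusted p under 0.05), 371 without WT experiment 2 and 0 with no FPKM filter (4399).

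The 585 RNAs more enriched in WT than in NF90+NF110 KO were taken as bound, to ask whether bound RNAs change in the mutants. Of these 380 were also above input in WT, 49 were below and 156 passed in neither direction. Phlda2 was bound and higher in NF45 KO (1.53), as was the growth factor carrier gene Igfbp2 (0.83), and Fkbp11 (-0.78) and the galectin gene Lgals1 (-0.51) were bound and lower. Of 1281 genes higher in NF45 KO 71 were bound against 61.5 expected (odds ratio 1.19, 95% interval 0.907 to 1.54, Fisher's exact p = 0.187). Of 1824 lower 88 were bound against 87.5 expected (odds ratio 1.01, 0.788 to 1.28, Fisher's exact p = 0.952). Of the 11 genes higher in NF90+NF110 KO 2 were bound, Selm and Crabp1 (odds ratio 4.52, 0.474 to 21.9, Fisher's exact p = 0.0916). Of the 15 lower 0 were bound (Fisher's exact p = 1). None of the 4 passed. The 2 tests in NF90+NF110 KO use the same WT and NF90+NF110 KO inputs that defined the bound RNAs, with the same sign. Part of any overlap with genes higher there is thus built in. Over all RNAs the r of that change with the enrichment difference was 0.488, against 0.38 in simulated values without any effect.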

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

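The 3 tests on chromosomes 6 and 8, the count of histone RNAs shared between 2 enrichment differences, the test of p53 targets in the NF90+NF110 KO inputs, the medians over library pairs of p53 targets and 2-cell genes, and the fits with the chromosome 6 term were chosen only after the results were seen.

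The change from input to IP differed between genotypes for 739 RNAs (WT against NF90+NF110 KO), 1258 RNAs (NF110 KO against NF90+NF110 KO) and 1694 RNAs (WT against NF110 KO), each by a test of the difference itself. The effect of losing NF45 differed from the effect of losing NF90 and NF110 for 1397 of 11226 genes (539 higher, 858 lower in NF45 KO) when the degrees of freedom came from both moderated variances (median 13.2). With 2 degrees of freedom limma's effects gave 0 such genes and with 8 they gave 778 (274 higher, 504 lower). The count turns on that choice, and this version was settled after the other 2 had been seen. The 2 effects come from different library kits, which this difference does not separate from the genes lost. Nor does it remove the shifts of chromosomes 6 and 8. Their medians were -0.48 and -0.50 in NF45 KO, against -0.03 and -0.004 in the NF90+NF110 KO inputs.

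Other splits of the same 6 libraries or 6 experiments into 3 and 3 number 10 with the real one, so no share under 0.1 can be had. Real count and highest other were 1 and 8 for NF110 KO inputs (2 of 10 splits gave as many), 26 and 1 for NF90+NF110 KO inputs (1 of 10), and 6 and 2243 for NF90+NF110 KO against NF110 KO inputs (2 of 10). The split with 2243 sets NF110 KO inputs 1 and 2 and NF90+NF110 KO input 2, those with high chromosome 6 levels, against the other 3, which points to a structure of the samples. For IP against input they were 6659 and 1 in WT, 4832 and 0 in NF110 KO and 5655 and 0 in NF90+NF110 KO. For the differences in enrichment they were 739 and 0, 1258 and 0, and 1694 and 1, in the order above. In each of these 6, 1 of 10 splits gave as many. For IP against input the low other counts were largely built in. The term for experiment was kept, so each other split parted only 1 of 3 pairs, or all 3 but not in the same direction. The real difference of IP and input then went into the spread, so these 3 comparisons exclude nothing.

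Genes of chromosomes 6 and 8 were lower in NF45 KO. A single aberrant library is argued against, since the highest of the 8 medians over pairs of a KO and a WT library was -0.448. Chromosome copy number differing between the cultures predicts a shift along the whole chromosome, and the highest median of the 15 bins of 20 Mb was -0.351, so copy number may account for it. Loss of NF45 as the cause stays open, as chromosome 6 medians also ranged over 0.503 among the 3 NF90/NF110 WT inputs, which share a genotype. Chromosome 8 did not vary so, with deviations between -0.020 and 0.033 over the 9 inputs, so this value bears on chromosome 6 only.

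The enrichment of 585 RNAs was higher in WT than in NF90+NF110 KO. After a trend against transcript length and level was removed, 4.4% of them (26) stayed called. The median difference went from 0.34 (median SE 0.074) to 0.20 (0.063), with 576 of 582 still positive. A bias of the immunoprecipitation with length and level may thus make up part of it. Removing the trend also removes any binding that follows length or level, so this cannot tell bias from binding. Without a single experiment the share that stayed called was as low as 2.1%, and under 10% for 4 of 6 experiments (WT 1 and 2, NF90+NF110 KO 1 and 3), while the medians lay between 0.318 and 0.386. The calls thus rest on each of several experiments. Binding of NF90 or NF110 stays open. In both WT and NF110 KO, 13 histone RNAs were called higher than in NF90+NF110 KO, but both differences share the NF90+NF110 KO libraries. Over all RNAs r was 0.342, against 0.503 in simulated values without any effect, but the covariance was 0.0156 against 0.0103 simulated. The simulation leaves out differences that many genes of a library share, so neither value decides. After the trend was removed, 1 of the 34 histone RNAs called in WT stayed called.

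The p53 targets and 2-cell genes were higher in NF45 KO. Of the 29 called members 96.6% (28) stayed called after each library was centred per chromosome. Being called higher nearly fixes this, since the shifted chromosomes were lower in NF45 KO and the other 16 had medians of at most 0.05. Those medians, rather than the centring, argue against whole-chromosome copy number raising these genes through their position. All 29 had both KO libraries above both WT libraries, which being called nearly fixes, but over all 23 measured p53 targets and all 23 2-cell genes with a value above 0, called or not, the lowest of the 4 medians over pairs of a KO and a WT library was 0.873 and 0.783, which argues against a single aberrant library. Loss of the complex may explain the p53 part, as 21 of 23 p53 targets had a higher mean in the NF90+NF110 KO inputs. Differences between clones other than NF45 itself, such as stress in culture or an indirect effect of changed chromosomes, were not tested.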

How the results depend on the processing

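The fits by edgeR and DESeq2 on recovered reads, those without chromosomes 6, 8, 13, 14 and Y, centred per chromosome or with the chromosome 6 term, those with only the libraries compared or the length and level trend removed, and the comparison with the authors' deposited table were chosen after seeing the data. Except where the construction shows it (fewer libraries or genes, a higher fold), the cause was not tested.

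Of 16083 values of 791 named results under the alternatives, 13902 stayed on the same side of the threshold. That count includes any value that changed sign but passed in neither fit. With direction kept, 1945 no longer passed and 230 newly passed. Another 6 reversed direction with a pass in the main or the alternative fit. The reversals in NF45 KO, all under centring per chromosome, were Nanog 0.17, Phc1 0.086, Elavl1 0.26, Ndufa4 0.0017, Ndufa9 0.15 and Rpl32 0.10.

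Asking for at least 2-fold left 368 genes in NF45 KO, 3 and 2 in NF90+NF110 KO inputs against WT (26 before) and NF110 KO (6), 125, 84 and 95 in the IPs of WT, NF110 KO and NF90+NF110 KO (6659, 4832, 5655), and 4, 1 and 18 in the differences of enrichment WT minus NF90+NF110 KO, NF110 KO minus NF90+NF110 KO and WT minus NF110 KO (739, 1258, 1694). For NF110 KO inputs (1) limma called 0 at a minimum FPKM of 5, at pseudocounts 0.1 and 0.01 and with a replicate block (1735, 2041, 2040 and 2597 at an unadjusted p under 0.05), and 2 after quantile scaling; edgeR called 0 (2114), DESeq2 272, the fit with the chromosome 6 term 717, and the authors' deposited table passes 554. For NF90+NF110 KO inputs the counts were 16 with no filter, 44 without trend and robust moderation, 48 with a replicate block, 42 without the 5 chromosomes, 309 by DESeq2, 1031 with the chromosome 6 term, 1 with only the libraries compared, and 655 in the authors' deposited table. Against NF110 KO they were 80 by DESeq2, 70 with the chromosome 6 term, 0 by limma with only the libraries compared (1083), and 140 in the authors' deposited table.

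For the IPs of WT, NF110 KO and NF90+NF110 KO, leaving out the replicate block gave 3491, 1865 and 2433, and the authors' deposited table passes 3600, 2043 and 2664. For WT minus NF90+NF110 KO limma gave 214 with no filter, 135 after quantile scaling, 0 without trend and robust moderation (2830) and 0 without the replicate block (965), edgeR gave 1173, and removing the trend 48. For NF110 KO minus NF90+NF110 KO the counts were 320 with no filter, 1 without trend and robust moderation, 1 without the replicate block, 1948 by edgeR and 723 with the trend removed. For WT minus NF110 KO limma gave 0 with no filter (4399), 501 without trend and robust moderation and 0 without the replicate block (1551).

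Leaving out a library or experiment gave 0 to 6035 in NF45 KO, where the lone library of an arm is assumed to vary like the other group (0 without either KO library, with 2291 and 2316 at an unadjusted p under 0.05). It gave 0 to 1 in NF110 KO inputs, 1 to 23 and 0 to 8 in NF90+NF110 KO inputs against WT and NF110 KO, 5344 to 6750, 3429 to 4879 and 4316 to 5717 in the IPs, and 13 to 1179, 6 to 1440 and 0 to 2416 in the differences. The r of NF45 KO and NF90+NF110 KO was 0.098 to 0.402 (jackknife SE 0.275), and that of NF110 KO and NF90+NF110 KO 0.295 to 0.671 (jackknife SE 0.334). Among the 15 genes past the threshold in both, the former was 0.922, a value largely fixed by that selection.

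Higher shares moved with scaling: in NF45 KO from 42.2% to 53.3% (1663 higher, 1455 lower) after median centring, 52.3% (1697, 1548) centred per chromosome and 54.5% without the 5 chromosomes. In NF110 KO inputs quantile scaling moved it from 100% to 50%, in WT minus NF90+NF110 KO from 79.2% to 55.6% (75, 60), and in NF110 KO minus NF90+NF110 KO from 60.6% to 44.3% (464, 583).

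Of the set tests 63 passed with the preset correlation and 0 with the estimated one, which also uses far fewer degrees of freedom. The odds ratio of bound RNAs among genes higher in NF45 KO was 1.38 (p = 0.0362, Fisher's exact) in the most expressed of 3 equal parts of the genes. With the chromosome 6 term it was 4.71 (Fisher's exact p = 1.7e-27) among genes higher and 0.32 (Fisher's exact p = 0.000221) among genes lower in NF90+NF110 KO. The bound RNAs were chosen with the same inputs and the same sign, so this association is partly built in and is no finding. Alternatives of this overlap with an infinite odds ratio, or with 0 shared RNAs where under 1 was expected, were not set against the main test.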

Other observations

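H2afy was low in both NF45 KO libraries, and its 10 nearest tested neighbours on chromosome 13 had log2 fold changes of -0.42 to 0.48, with 0 passing by limma. The NF45 WT pair was less alike (r = 0.991) than the NF45 KO pair (r = 0.998). The first 2 principal components of the RIP-seq libraries held 33.1% and 28.9% of the variance.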
